A study of Homo sapiens with 6 samples.

How the data were processed

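Small RNA was sequenced from A2780, a human ovarian cancer cell line labelled cisplatin-sensitive, and from A2780-DDP, a line labelled cisplatin-resistant, with 3 libraries of each. Per the labels, both lines were grown in the same medium with no special treatment, RNA was extracted with TRIzol and libraries were made with a VAHTS small RNA kit. fastp 0.20.0, BWA 0.7.13 and the GRCh38 genome are named per the submitters' processing notes, without their roles. The miRNA annotation release, the counting tool, its use of strand and its treatment of reads that match several hairpins are not given in the sources used here.

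The deposited table lists 2796 mature miRNAs, of which 2656 carry miRBase names and 140 are predicted miRNAs with no miRBase name. Its name calls the values TPM, but each deposited column sums to 1e+06 and its values are whole multiples of 1 step that is shared by every miRNA of the library. The deposited values were therefore treated as RPM (reads scaled to a library total of 1e+06), scaled by the authors to the reads assigned to the listed miRNAs with no division by length. Dividing by that step gave whole reads for 100% of the 8502 values above 0, within a tolerance of 0.01 reads. The recovered totals were 3268371, 3735634 and 3930546 reads in A2780 replicates 1, 2 and 3, and 1327319, 3297470 and 3476038 reads in A2780-DDP replicates 1, 2 and 3. A single read was therefore worth from 0.254 RPM in A2780 replicate 3 to 0.753 RPM in A2780-DDP replicate 1. Where a count of 0 is given, its limit is 3 reads, which is 0.763 to 2.26 RPM depending on the library. Intervals and such limits cover counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules.

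Table columns were matched to libraries by the initials of the line and the replicate number. No label says that the libraries of a line came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Libraries of each line were compared by a chi-square test of their recovered reads, and each pair differed by more than sampling noise.

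The following choices were made before the data were examined. The 2 lines were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend, two-sided) on log2(RPM + 1), over miRNAs with at least 10 RPM in at least 3 libraries, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A log2 fold change is on the log2(RPM + 1) scale, which understates the change of low miRNAs, and is positive where A2780-DDP was higher. Fold changes printed for single miRNAs were back-transformed from it, so they can differ from the ratio of the mean RPM. The filter left 405 miRNAs, which held 99.79% of the reads. Lists of miRNAs, 30 in all, were tested with limma's camera (correlation preset at 0.01) where at least 3 members passed the filter, and with fry. The main test of fry asks whether members move on balance in 1 direction. The ratio of both arms of a hairpin was tested with limma on log2(5p RPM + 1) minus log2(3p RPM + 1). Numbers of miRNAs detected and shares of the total were compared by exact two-sided permutation tests, for which 3 against 3 libraries cannot give a p below 0.1. The lists covered the miR-219 hairpins, the let-7, miR-200, miR-34, miR-29, miR-30, miR-15, miR-181, miR-10, miR-196 and miR-130 families, the miR-183, miR-17-92, miR-192, miR-450, miR-532, miR-506, miR-221 and miR-23 clusters, the imprinted cluster on 14q32, the primate cluster on 19q13, pluripotency miRNAs, miRNAs often studied in the cisplatin response of ovarian cancer, miRNAs of blood, stroma, endothelium, striated muscle, liver and neural cells, and entries that overlap abundant structural RNA.

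The miRNAs named in the text were set by a rule. They are every miR-219 entry, the 12 largest increases and the 12 largest decreases among miRNAs past the threshold with a mean of at least 10 RPM and no overlap between the lines, the 5 most abundant miRNAs of each line, up to 4 tested members of each list with the highest mean, and the 3 hairpins of smallest p in each direction if the arm test passed its threshold. Any other miRNA is marked as chosen after its values were seen.

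Alternatives covered the replicate number as a block, the pseudocount, the filter, leaving out each library, median-of-ratios factors, rescaling without the 5 most abundant miRNAs, quantile normalization, the variance model, the threshold, and edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads. Hairpin positions, strands and host genes were taken from the GENCODE annotation of GRCh38, and GC content from GENCODE transcript sequences. RefSeq synonyms served only to match names. Names of 2576 listed miRNAs, and of 392 of the 405 tested, matched a hairpin gene. The 138 predicted miRNAs below the filter of 10 RPM entered no test with that filter. On simulated values for 405 miRNAs, of which 60 were changed, limma recovered 22.5% of 2-fold, 79% of 4-fold and 98.2% of 8-fold changes over 20 simulations, with 5.11% false calls. In the same simulations edgeR recovered 22.2%, 80.8% and 99%. Simulated counts were scaled by the real library totals, with as many folds up as down and no library set apart. The figures for single miRNAs do not cover a shift of the per-million total or an outlying library. The 5.11% is therefore not a false-call rate for the real data. A 3-fold shift of a list was recovered in 100% of simulations, and an 8-fold shift of an arm ratio over 99 hairpins in 92%. Simulated miRNAs were drawn independently and put into lists at random. The list figure therefore does not cover members that are correlated, and does not give the power for the real lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.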

Results

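Mature miRNAs were measured by small RNA sequencing in 3 libraries of A2780, an ovarian cancer line sensitive to cisplatin, and 3 libraries of A2780-DDP, a line resistant to it. The libraries held between 1327319 and 3930546 reads assigned to miRNAs, the fewest in A2780-DDP replicate 1. At least 1 RPM was found for 869 ± 87.2 miRNAs in A2780 and 914 ± 100 in A2780-DDP (SD, n = 3 each), a difference within the spread between libraries (exact permutation p = 0.7). That difference of 45.3 miRNAs turned to -10.3 with a limit of 10 RPM, to -44.7 when any read counted, and to -12.5 without A2780-DDP replicate 1, the library with the fewest reads.

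The question of the series, going by its title, concerned miR-219-5p, whose present miRBase name is miR-219a-5p. It was rare in both lines, at 2.45, 1.34 and 2.29 RPM in the A2780 libraries (2.03 ± 0.60, SD, n = 3) and 0.753, 0 and 1.15 RPM in the A2780-DDP libraries (0.635 ± 0.585, SD, n = 3). These values rest on 22 reads in A2780 and 5 reads in A2780-DDP, the latter 1, 0 and 4 in replicates 1, 2 and 3. The ratio of pooled RPM, A2780-DDP over A2780, was 0.307, with an exact 95% Poisson interval from 0.0908 to 0.830 that covers counting error only. All 3 A2780-DDP libraries lay below all 3 A2780 libraries, and the exact permutation p of 0.1 is the smallest that this design can give. The mature form can come from 2 hairpins, MIR219A1 on chromosome 6 (33207835 to 33207944, plus strand, GRCh38), which lies between genes, and MIR219A2 on chromosome 9 (128392618 to 128392714, minus strand), in an exon of the long noncoding RNA AL359091.1. The opposite arm from the chromosome 6 hairpin, miR-219a-1-3p, was more abundant, at 33.5 ± 3.26 RPM in A2780 and 48.5 ± 10.5 RPM in A2780-DDP (SD, n = 3 each, log2 fold change 0.50, SE 0.34), and did not pass the threshold (limma, Benjamini-Hochberg adjusted p = 0.356). The pooled ratio of miR-219a-1-3p, on 368 reads in A2780 and 383 in A2780-DDP, was 1.405. Its exact 95% Poisson interval, from 1.214 to 1.625, again covers counting error only, and lies on the opposite side of 1 from that of miR-219a-5p. From the chromosome 9 hairpin, miR-219a-2-3p had 6 and 12 reads in A2780 and A2780-DDP. Its antisense neighbour MIR219B (128392621 to 128392708, plus strand) gave 9 and 12 reads of miR-219b-5p, which cannot be told apart from antisense reads of MIR219A2 if strand was not used, and miR-219b-3p had 0 reads in every library. Because miR-219a-5p was below the filter of 10 RPM it entered the limma test only with lower filters. Its log2 fold change there was -0.94 (SE 0.60 with no filter), with a Benjamini-Hochberg adjusted p of 0.291 with a filter of 1 RPM and 0.58 with no filter. edgeR and DESeq2 on the recovered reads gave -1.52 (adjusted p = 0.625) and -1.34 (adjusted p = 0.764), so none of the 3 tools placed it past the threshold at this depth.

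A small set of miRNAs was strongly higher in A2780-DDP. Both arms of miR-30a rose, miR-30a-5p from 13.96 ± 2.06 to 205 ± 93.2 RPM (12.8-fold, log2 fold change 3.68, SE 0.40) and miR-30a-3p from 16.2 ± 1.72 to 97.6 ± 11.3 RPM (SD, n = 3 for these and all further means). The smooth-muscle-associated pair miR-143-3p and miR-145-5p rose as well, miR-143-3p from 849 ± 631 to 3845 ± 1790 RPM (5.06-fold) and miR-145-5p from 14.2 ± 14.4 to 54.9 ± 9.97 RPM. Without A2780 replicate 3 their A2780 means were 489 and 5.93 RPM. miR-6849-5p had 3 reads in all of A2780 and 237 in A2780-DDP (25.2 ± 18.3 RPM), a pooled ratio of 107 with an exact 95% interval from 36.1 to 521 for counting error only. All 3 A2780 reads were in replicate 3, and 159 of the 237 A2780-DDP reads were in replicate 3, without which the ratio was 61.5 (20.3 to 305). Next came miR-3118, from 6.02 ± 0.296 to 49.9 ± 16.5 RPM (7.02-fold), and miR-5701, from 46.4 ± 12.8 to 361.8 ± 200.1 RPM (6.73-fold). The other large increases were miR-4423-5p (2.60 to 17.8 RPM), miR-4634 (5.59 to 27.7 RPM), miR-574-3p (106 to 312 RPM), miR-100-5p, a regulator of mTOR (18.9 to 66.9 RPM), and miR-23b-5p (40.5 to 109 RPM). The A2780-DDP mean of miR-100-5p was 43.2 RPM without replicate 2. limma gave these 12 miRNAs Benjamini-Hochberg adjusted p-values from 0.000482 for miR-30a-5p to 0.0379 for miR-100-5p. miR-30a lies on chromosome 6 (71403551 to 71403621, minus strand), in an intron of the long noncoding RNA AL136164.2. miR-143 and miR-145 lie on chromosome 5 (149428918 to 149429023 and 149430646 to 149430733, plus strand), in an exon and an intron of the long noncoding RNA CARMN. miR-6849 overlaps an exon of CPSF1 on chromosome 8 (144400277 to 144400345, minus strand).

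The decreases in A2780-DDP were led in abundance by miR-148a-3p, a repressor of the DNA methyltransferase DNMT1, which fell from 75450 ± 14830 to 7917 ± 3194 RPM. That change was 9.89-fold (log2 fold change -3.31, SE 0.30, limma Benjamini-Hochberg adjusted p = 0.000219), and the miRNA went from 7.54% to 0.792% of all miRNA reads. Its partner arm miR-148a-5p fell 12.9-fold, from 680 ± 104 to 56.5 ± 30.9 RPM. All 4 arms of the neighbouring CREB-responsive hairpins miR-132 and miR-212 fell. The miR-132 arms fell from 960.5 ± 194.4 to 202 ± 67.3 RPM for miR-132-3p and from 788 ± 122 to 88.0 ± 34.8 RPM for miR-132-5p. The miR-212 arms fell from 245 ± 13.1 to 38.0 ± 13.8 RPM for miR-212-5p and from 67.7 ± 9.90 to 11.03 ± 6.39 RPM for miR-212-3p. miR-200a, which represses the mesenchymal transcription factors ZEB1 and ZEB2, fell in both arms, from 33.6 ± 10.4 to 4.18 ± 4.58 RPM for miR-200a-3p and from 42.1 ± 7.68 to 5.32 ± 4.34 RPM for miR-200a-5p. miR-204-5p had the most negative log2 fold change (-3.91, SE 0.79) among the named miRNAs, from 119 ± 15.4 to 13.6 ± 18.3 RPM. Its A2780-DDP mean rests on replicate 2 (34.6 RPM) and was 3.05 RPM without it, and edgeR did not call it (-2.66, Benjamini-Hochberg adjusted p = 0.0729). Without A2780-DDP replicate 2 the A2780-DDP means also fell to 1.56 RPM for miR-200a-3p, 2.98 RPM for miR-200a-5p and 7.18 RPM for miR-4661-5p. miR-629-5p (388 to 85.7 RPM), miR-4661-5p (53.6 to 12.9 RPM) and miR-3158-5p (187 to 43.1 RPM) completed the group. In limma their Benjamini-Hochberg adjusted p-values reached at most 0.017, for miR-4661-5p. miR-148a lies between genes on chromosome 7 (25949919 to 25949986, minus strand). miR-132 and miR-212 lie between genes on chromosome 17 (2049908 to 2050008 and 2050271 to 2050380, minus strand), and miR-200a on chromosome 1 (1167863 to 1167952, plus strand). The miR-204 hairpin lies in an intron of TRPM3 on chromosome 9 (70809975 to 70810084, minus strand).

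**Figure D1:**
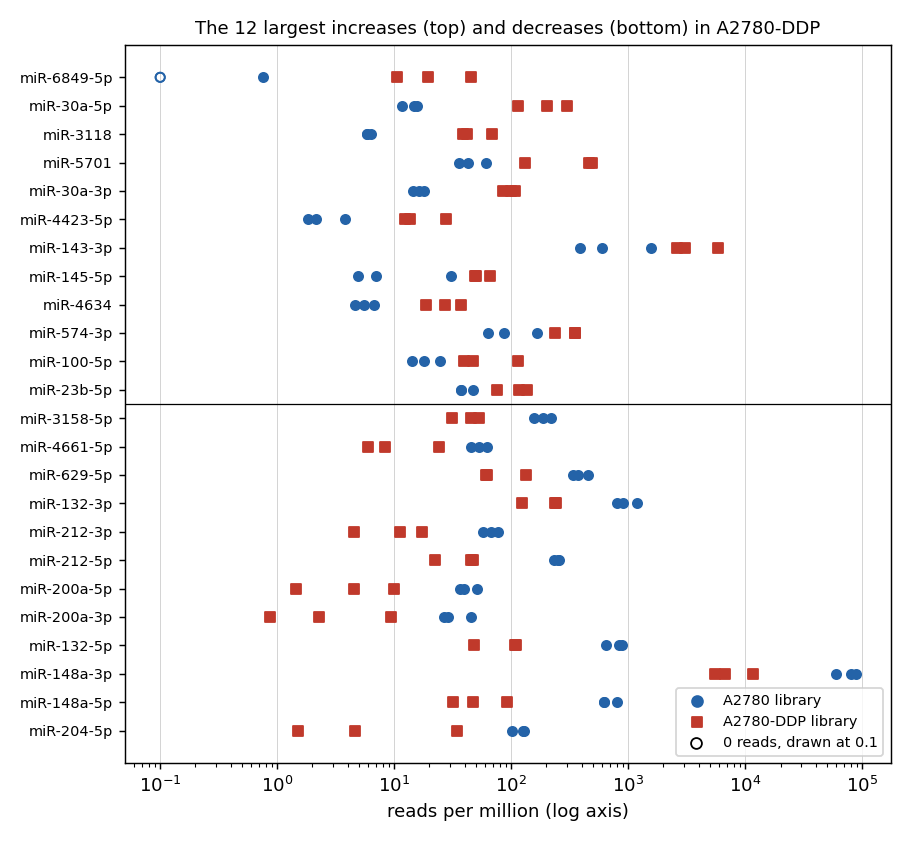
RPM of the 12 largest increases and 12 largest decreases in each library, on a log axis, with circles for the 3 A2780 libraries and squares for the 3 A2780-DDP libraries; an open circle marks 0 reads and is drawn at 0.1. For every miRNA shown the libraries of both lines are fully apart, as for miR-148a-3p, with means of 75450 and 7917 RPM, and miR-30a-5p, with means of 13.96 and 205 RPM.

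In all, 56 of 405 tested miRNAs passed the threshold in limma, 14 higher and 42 lower in A2780-DDP. The libraries of both lines did not overlap for any of the 56, and 150 of the 405 tested miRNAs had lines that did not overlap, where chance gives 10%. The median log2 fold change of all tested miRNAs was -0.43 in deposited RPM and -0.08 after rescaling by median-of-ratios factors, so a fold change near -0.43 equals that of the typical miRNA. Rescaled in that way, 17 miRNAs were higher and 24 lower, 38 of these calls were shared with the deposited scale, and none of the 56 changed direction. edgeR on the recovered reads called 23 higher and 20 lower, and DESeq2 called 34 higher and 28 lower. Of the 24 miRNAs with the largest changes, 13 passed in every alternative in which they were tested, namely miR-6849-5p, miR-30a-5p, miR-30a-3p, miR-3118, miR-5701, both arms of miR-148a, miR-132 and miR-212, miR-629-5p and miR-3158-5p. The other 11 each lost their call on leaving out at least 1 library (highest adjusted p = 0.145, limma, Benjamini-Hochberg). Of these 11, 9 lost it without A2780 replicate 1, 10 without A2780 replicate 2, 3 without A2780 replicate 3, 3 without A2780-DDP replicate 1 and 9 without A2780-DDP replicate 3. edgeR did not call 3 of them, miR-204-5p, miR-200a-3p and miR-4661-5p. A2780-DDP replicate 2 stood apart from replicates 1 and 3 (Pearson r over tested miRNAs 0.919 and 0.927, against 0.985 between those 2), and without it 131 miRNAs passed, 29 higher and 102 lower, among them all 56. With median-of-ratios factors the split without that library was 56 higher and 62 lower, in a fit chosen after the data were seen. Of the miRNAs named below as not past the threshold, 15 passed without that library in deposited RPM. They were miR-27b-3p, miR-183-5p, miR-92a-3p, miR-25-3p, miR-30e-3p, miR-450a-5p and miR-450b-5p, which were higher, and miR-200b-3p, miR-30d-5p, miR-222-3p, both arms of miR-221, miR-99b-5p, miR-1260b and miR-1246, which were lower. The count was 23 without A2780 replicate 1, 17 without A2780 replicate 2, 37 without A2780 replicate 3 and 23 without A2780-DDP replicate 3.

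**Figure D2:**
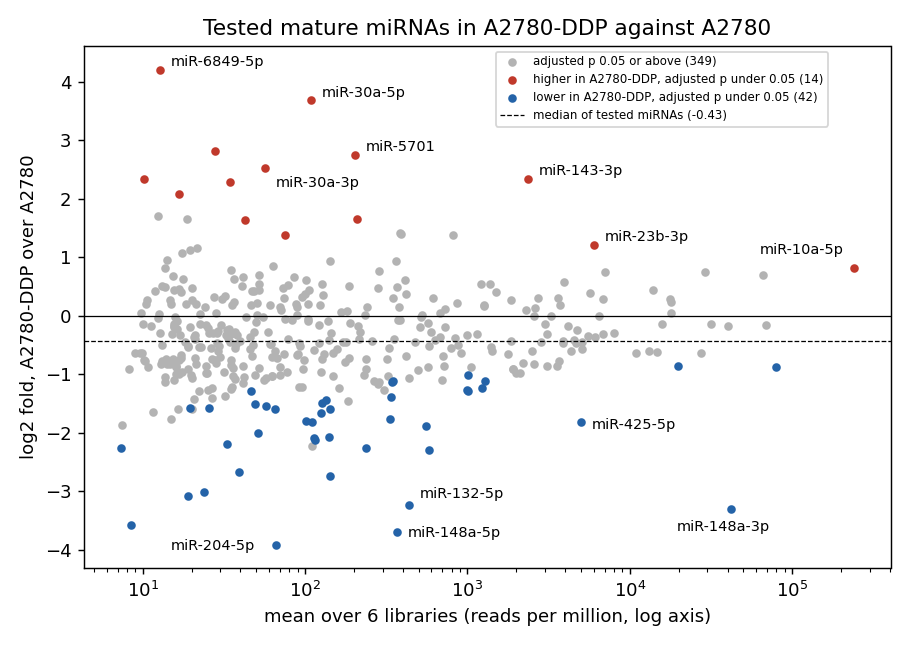
Log2 fold change of A2780-DDP over A2780 against mean RPM over 6 libraries (log axis) for 405 tested miRNAs, with 1 point per miRNA coloured by direction where the limma adjusted p was under 0.05. The 14 higher and 42 lower miRNAs lie around a dashed line at the median of -0.43, and miR-10a-5p, higher at the right edge, is the most abundant.

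The most abundant miRNA of both lines, miR-10a-5p, encoded in an intron of HOXB3 on chromosome 17 (48579838 to 48579947, minus strand), rose from 173500 ± 10480 to 305600 ± 19610 RPM. This 1.76-fold change (log2 fold change 0.82, SE 0.15, limma Benjamini-Hochberg adjusted p = 0.00529) took it from 17.4% ± 1.05 to 30.6% ± 1.96 of all miRNA reads. The per-million scale turns that rise alone into a shift of -0.25 (log2) in every other miRNA. The call did not pass without A2780 replicate 2 (limma Benjamini-Hochberg adjusted p = 0.0557), with no filter (0.06745) or with a variance model without trend (0.09985). A required log2 fold change of at least 1 leaves it out by definition. Quantile normalization cannot show a change of miR-10a-5p, since it gives the top-ranked miRNA of every library the same value. miR-151a-3p fell from 101600 ± 4712 to 57220 ± 18130 RPM (log2 fold change -0.87, adjusted p = 0.0278 in limma with Benjamini-Hochberg adjustment), and lost its call with median-of-ratios factors (-0.52, adjusted p = 0.26), in edgeR and DESeq2, and on leaving out any library but A2780-DDP replicate 2. miR-148a-3p, also among the 5 most abundant of A2780, fell as given above. The other leading miRNAs did not pass in limma, with miR-21-5p at 71900 ± 13470 and 66860 ± 23250 RPM, miR-27b-3p at 47280 ± 9307 and 84640 ± 41050 RPM, and miR-199a-5p at 41170 ± 6840 and 39270 ± 17240 RPM. DESeq2 called miR-27b-3p (Benjamini-Hochberg adjusted p = 0.0359). Together the 10 most abundant miRNAs of a library held 62.7% ± 3.02 of reads in A2780 and 68.4% ± 0.792 in A2780-DDP (exact permutation p = 0.1, the smallest possible with n = 3).

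**Figure D3:**
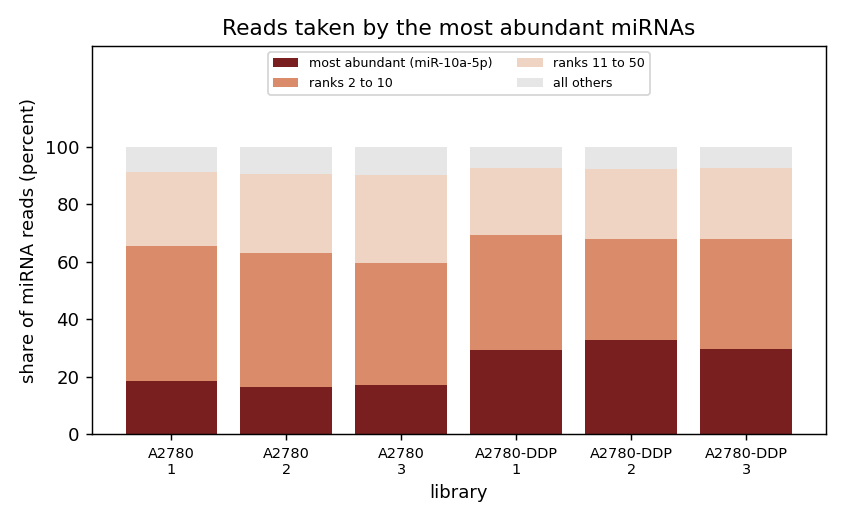
Share of miRNA reads in percent, stacked for each of the 6 libraries, held by the most abundant miRNA, by ranks 2 to 10, by ranks 11 to 50 and by all others. The darkest part, miR-10a-5p, averages 17.4% in A2780 and 30.6% in A2780-DDP.

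Of the 30 lists, 20 had at least 3 tested members, and camera placed the let-7 family and the miR-23 clusters (miR-23, miR-27 and miR-24) past the threshold, each higher in A2780-DDP relative to the other miRNAs (Benjamini-Hochberg adjusted p = 0.0435 for both). With an estimated correlation both calls were lost (adjusted p = 0.936 for each), and with no filter they were lost as well (0.201 for each). In its test of 1 direction fry called 0 of 20 lists, with 6 at an unadjusted p under 0.05. For members changing in either direction, fry gave an unadjusted p of 0.0012 for the miR-23 list and 0.31 for let-7. The lowest p of that kind was 4.7e-06, for the miR-30 list. None of the 13 tested let-7 members passed on its own, over all miRNAs or when adjusted over the list alone. All 13 lay above the median log2 fold change of the tested miRNAs (-0.427). For let-7i-5p (-0.423) the margin was slight, and its mean RPM was lower in A2780-DDP. In limma 1 of the 13 had an unadjusted p under 0.05, and edgeR called 1 and DESeq2 2 of them. Examples of this family, known for repressing RAS and LIN28, were let-7a-5p (5022 ± 969 and 8949 ± 4233 RPM), let-7f-5p (3158 ± 340 and 4753 ± 738 RPM), let-7g-5p (4415 ± 625 and 3955 ± 1031 RPM) and let-7i-5p (2110 ± 390 and 1600 ± 448 RPM). The summed family was 30570 RPM in A2780-DDP replicate 2, against 18070 and 18640 RPM in replicates 1 and 3, and the call was lost without that library (adjusted p = 0.303 in camera, Benjamini-Hochberg) or without any of the A2780 libraries (0.0506 to 0.0584). In the miR-23 list 2 of 10 tested members rose, and 2 rose and 1 fell when adjusted over the list alone. The increases were miR-23b-3p (3611 ± 850 to 8336 ± 1614 RPM) and miR-23b-5p, from the hairpin on chromosome 9 (95085208 to 95085304, plus strand) in an intron of C9orf3. The abundant members miR-24-3p (6322 ± 398 and 6599 ± 2465 RPM) and miR-27a-3p (2484 ± 2364 and 2981 ± 2691 RPM, or 1122 and 1430 RPM without replicate 1 of each line) did not pass. edgeR called 2 of the 10 and DESeq2 4, adding miR-27b-3p and miR-23a-3p (named after its values were seen). The list call was lost without A2780 replicate 2 or 3 or A2780-DDP replicate 1 or 2 (camera adjusted p from 0.0506 to 0.166, Benjamini-Hochberg), and with median-of-ratios factors (0.051). The call of miR-23b-3p was lost without A2780 replicate 1 or 2 or A2780-DDP replicate 1 or 3.

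Of 7 tested members of the epithelial miR-200 family, 2 fell over all miRNAs, both from miR-200a, and 4 fell when adjusted over the list alone (camera adjusted p = 0.195, Benjamini-Hochberg). edgeR called 1 and DESeq2 2 of the 7. With no filter the list passed lower in camera (9 members, adjusted p = 3.69e-05, Benjamini-Hochberg), but not with an estimated correlation (0.639). miR-200b-3p, from the hairpin beside miR-200a, was at 167 ± 62.5 and 54.3 ± 65.4 RPM. Its A2780-DDP values were 15.1, 129.8 and 18.1 RPM, with a mean of 16.6 RPM without replicate 2, where it passed (limma Benjamini-Hochberg adjusted p = 6.2e-05). Other members were miR-141-3p at 299.9 ± 76.5 and 218.9 ± 20.6 RPM and miR-141-5p at 137 ± 59.7 and 54.7 ± 10.4 RPM. The dominant member miR-200c-3p did not pass, at 15860 ± 1576 and 19830 ± 8682 RPM, and reached 29740 RPM in A2780-DDP replicate 2. In the miR-30 family 2 of 10 members rose in limma, both from miR-30a, and the same number when adjusted over the list alone (camera adjusted p = 0.051, Benjamini-Hochberg). Its most abundant members were miR-30d-5p (17880 ± 1951 and 11610 ± 1229 RPM), miR-30c-5p (1278 ± 103 and 1705 ± 319 RPM), miR-30e-3p (392.2 ± 25.4 and 1227 ± 733 RPM) and miR-30e-5p (846 ± 248 and 560 ± 263 RPM). edgeR and DESeq2 each called 3 members, adding miR-30e-3p (Benjamini-Hochberg adjusted p = 0.0303 and 0.000257), which stood at 385 RPM in A2780-DDP replicate 2 against 1576 and 1720 RPM in replicates 1 and 3. The summed family was 20760 ± 2070 RPM in A2780 and 15710 ± 2202 RPM in A2780-DDP. The list's median log2 fold change of -0.03 and its mean of 0.57 differ in sign. The miR-30 list passed in camera without A2780-DDP replicate 2 (adjusted p = 0.0171, Benjamini-Hochberg) or without A2780 replicate 1 (0.0443), and with pseudocount 0.1 or no filter (0.0488 for each). With an estimated correlation it did not, at 0.936 over all libraries, 0.649 without A2780-DDP replicate 2 and 0.639 with no filter. In the miR-130, miR-148 and miR-152 list both arms of miR-148a fell among 15 tested members, also when adjusted over the list alone. Its members miR-148b-3p (8404 ± 272 and 7623 ± 3670 RPM), miR-152-3p (681 ± 341 and 516 ± 36.5 RPM) and miR-130a-3p (366 ± 38.9 and 471 ± 48.1 RPM) did not pass. edgeR called 2 of the 15 and DESeq2 4. The list of the miR-10, miR-99, miR-100 and miR-125 families had 2 increases, miR-10a-5p and miR-100-5p, and 1 decrease, miR-99b-3p (1757 ± 227 to 811 ± 132 RPM), among 9 tested members, with the same counts when adjusted over the list alone. edgeR and DESeq2 each called 3 of the 9, without miR-99b-3p and with miR-10b-5p (named after its values were seen). miR-99b-5p (33130 ± 4934 and 21710 ± 6424 RPM) and miR-125a-5p (2058 ± 171 and 2544 ± 1685 RPM) did not pass over all libraries. The A2780-DDP mean of miR-125a-5p rests on replicate 2 (4454 RPM) and was 1589 RPM without it, below that of A2780. miR-99b-3p lost its call with median-of-ratios factors (limma adjusted p = 0.13, Benjamini-Hochberg) and on leaving out any library but A2780-DDP replicate 2.

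In the miR-15 family 2 of 10 members fell in limma, and 3 when adjusted over the list alone. 1 of them was miR-195-3p (156 ± 19.9 to 45.9 ± 15.1 RPM). Its call was lost without A2780 replicate 1 or 2 or A2780-DDP replicate 3. By contrast miR-16-5p (668 ± 43.1 and 696 ± 107 RPM), miR-16-2-3p (216 ± 94.5 and 357 ± 122.9 RPM) and miR-15b-5p (234 ± 58.2 and 328 ± 86.3 RPM) did not pass in limma. edgeR called 2 of the 10, and DESeq2 called 3, adding miR-16-2-3p (Benjamini-Hochberg adjusted p = 0.0309). The other was miR-503-5p, chosen after its values were seen (97.4 ± 3.69 to 32.7 ± 9.66 RPM), which was also the only decrease among 6 members of the miR-450 cluster on chromosome X, over all miRNAs and when adjusted over the list alone. Its neighbours there did not pass, with miR-542-3p at 186 ± 23.6 and 192 ± 99.3 RPM, miR-450b-5p at 73.6 ± 26.2 and 129 ± 76.0 RPM, miR-424-3p at 88.4 ± 4.95 and 90.9 ± 19.4 RPM, and miR-450a-5p at 76.3 ± 4.08 and 100.6 ± 52.8 RPM. Among 5 members of the miR-29 family 1 fell, miR-29c-5p (72.1 ± 8.08 to 25.8 ± 9.24 RPM), also when adjusted over the list alone, and its call was lost with median-of-ratios factors (limma adjusted p = 0.0817, Benjamini-Hochberg), in edgeR and in DESeq2. Without A2780 replicate 1, 2 or 3 or A2780-DDP replicate 3 it was lost as well. miR-29a-3p (2788 ± 643 and 1584 ± 338 RPM), miR-29b-3p (137 ± 52.1 and 109 ± 63.3 RPM) and miR-29a-5p (21.0 ± 3.38 and 13.3 ± 6.92 RPM) did not pass. Among the 36 tested miRNAs often studied in the cisplatin response of ovarian cancer 1 rose, miR-100-5p, and 1 fell, miR-214-5p (1436 ± 311 to 583 ± 42.0 RPM, chosen after its values were seen), with 0 calls in limma when adjusted over the list alone, where 6 had an unadjusted p under 0.05. edgeR called 1 and DESeq2 2 of the 36, and with median-of-ratios factors miR-214-5p did not pass (limma adjusted p = 0.119, Benjamini-Hochberg). The values of miR-214-5p were near-equal to those of the antisense miR-3120-3p, as given below. This cisplatin list was compiled from general knowledge, without a direction. Its most abundant members, miR-21-5p, miR-199a-5p, miR-199a-3p (32940 ± 780 and 30340 ± 7351 RPM) and miR-200c-3p, did not pass.

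No member of 7 further lists passed in limma, whether over all miRNAs or adjusted over the list alone. Of their 48 tested members 7 had an unadjusted p under 0.05 in limma, and edgeR and DESeq2 each called 2, miR-92a-3p and miR-183-5p. The oncogenic miR-17-92 cluster and its paralogues had 18 tested members, such as miR-92a-3p (21840 ± 6009 and 35990 ± 5134 RPM), miR-25-3p (4790 ± 823 and 6603 ± 2608 RPM), miR-20a-5p (5992 ± 1254 and 4209 ± 1515 RPM) and miR-17-5p (5807 ± 1294 and 4291 ± 984 RPM). With no filter the miR-17-92 list passed lower in camera (adjusted p = 0.0488, Benjamini-Hochberg), but not with an estimated correlation (0.670). With median-of-ratios factors miR-92a-3p rose (log2 fold change 1.10, adjusted p = 0.0152, limma with Benjamini-Hochberg adjustment). The miR-183 cluster had 4, among them miR-182-5p (15800 ± 835 and 19290 ± 2326 RPM), miR-183-5p (11650 ± 641 and 15950 ± 2515 RPM), miR-96-5p (915 ± 244 and 523 ± 212 RPM) and miR-183-3p (23.96 ± 4.38 and 21.4 ± 2.41 RPM). The miR-532 cluster had 11, led by miR-532-5p (3392 ± 187 and 3996 ± 1291 RPM), miR-500a-3p (391.7 ± 22.9 and 312 ± 105 RPM), miR-501-3p (234 ± 57.5 and 232 ± 23.8 RPM) and miR-362-5p (185 ± 11.2 and 128 ± 35.5 RPM). The p53-regulated miR-192 cluster had 3, which were miR-192-5p (1109 ± 220 and 712 ± 122 RPM), miR-194-5p (67.8 ± 14.7 and 74.4 ± 27.1 RPM) and miR-215-5p (33.7 ± 7.20 and 19.6 ± 0.954 RPM). The miR-181 family had 5, among them miR-181d-5p (94.8 ± 25.2 and 112 ± 41.5 RPM), miR-181a-2-3p (87.2 ± 19.8 and 113 ± 26.1 RPM), miR-181b-5p (57.0 ± 12.4 and 65.2 ± 15.3 RPM) and miR-181a-5p (31.6 ± 8.43 and 50.8 ± 14.2 RPM). The miR-181 list passed higher in camera without A2780 replicate 1 (adjusted p = 0.0474, Benjamini-Hochberg), and stood at 0.936 with an estimated correlation over all libraries. The HOX-encoded miR-196 list had 4, which were miR-615-3p (7510 ± 544 and 6121 ± 974 RPM), miR-196a-5p (3159 ± 455 and 2864 ± 238 RPM), miR-196a-3p (46.1 ± 11.1 and 45.7 ± 31.0 RPM) and miR-615-5p (34.66 ± 4.59 and 24 ± 4.68 RPM). miR-221 and miR-222, which repress the cell cycle inhibitor p27, had 3 tested arms, miR-222-3p (634 ± 109 and 507 ± 553 RPM), miR-221-3p (604 ± 88.0 and 395 ± 334 RPM) and miR-221-5p (169 ± 52.1 and 127 ± 102 RPM). Their sum was 2171 RPM in A2780-DDP replicate 2 against 414 and 510 RPM in replicates 1 and 3, and all 3 arms passed as lower without replicate 2. From the miR-34 family only miR-34c-5p was tested (14.7 ± 7.30 and 19.7 ± 9.67 RPM) and did not pass.

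Markers of other cell types and of RNA quality were measured alongside. Of 8 tested stromal miRNAs 2 rose, miR-143-3p and miR-145-5p, and 1 fell, miR-214-5p, with the same counts when adjusted over the list alone. edgeR and DESeq2 each called only the 2 increases. The stromal members miR-199a-5p, miR-199a-3p, miR-199b-3p (16400 ± 347 and 15070 ± 3546 RPM) and miR-199b-5p (4884 ± 354 and 4233 ± 2610 RPM) did not pass (camera adjusted p = 0.633 for the list, Benjamini-Hochberg). Blood markers were represented only by both arms of miR-486, with miR-486-5p at 140 ± 74.7 and 628 ± 809 RPM and miR-486-3p at 140 ± 68.5 and 637 ± 830 RPM. miR-486-5p stood at 1561 RPM in A2780-DDP replicate 2 and between 72.2 and 220 RPM in the other libraries. The endothelial miR-126-3p was at 593 ± 84.7 and 546 ± 96.8 RPM. Of 7 neural members 0 passed in limma (0 at an unadjusted p under 0.05, 0 called by edgeR and 1 by DESeq2), among them miR-9-5p (1213 ± 111 and 1081 ± 516 RPM), miR-137-3p (111 ± 19.9 and 147 ± 53.2 RPM), miR-338-5p (43.2 ± 14.1 and 49.3 ± 15.5 RPM) and miR-129-5p (40.6 ± 10.7 and 22.5 ± 12.2 RPM). Of 7 entries that overlap structural RNA 0 passed in limma (2 at an unadjusted p under 0.05, 0 called by edgeR or DESeq2), among them miR-1260a (2574 ± 187.6 and 2584 ± 463 RPM), miR-1260b (1689 ± 204 and 1147 ± 353 RPM), miR-1246 (256 ± 105 and 113 ± 100.5 RPM) and miR-7977 (100.9 ± 13.4 and 53.8 ± 20.7 RPM). Without A2780-DDP replicate 2 (228 RPM) the A2780-DDP mean of miR-1246 was 55.0 RPM, and miR-1246 and miR-1260b passed as lower (limma Benjamini-Hochberg adjusted p = 0.000942 and 0.0192). The lists of striated muscle, liver, pluripotency, miR-506, 14q32 and 19q13 miRNAs had 0 members above the filter.

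Arms of 99 hairpins were compared within each library, a ratio that library scaling leaves nearly untouched. limma placed 0 of 99 hairpins past the threshold, with 18 at an unadjusted p under 0.05, and no other tool was run on these ratios. Some ratios repeat others, since near-equal rows mirrored miR-423 (1.07) in miR-3184 (-1.09) and miR-214 (-0.84) in miR-3120 (0.80). These hairpins were named after their values were seen. Both miR-423 and miR-3184 are among the 18, and both also passed without A2780-DDP replicate 2. In miR-3158 and miR-486 both arms held near-equal values. The smallest p belonged to miR-30e, chosen after its values were seen, whose log2 ratio of 5p to 3p arm was 1.06 ± 0.559 in A2780 and -0.99 ± 0.44 in A2780-DDP (n = 3 each, limma Benjamini-Hochberg adjusted p = 0.0806). Without A2780-DDP replicate 2, 18 hairpins passed, led by miR-25 (also chosen after its values were seen) and miR-30e (-2.28 on the log2 scale), each with an adjusted p of 0.00359 in limma with Benjamini-Hochberg adjustment.

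In 8 pairs of tested miRNAs the values lay within 10% of each other in all 6 libraries, a search that named miRNAs after their values were seen. They were miR-214-3p with miR-3120-5p, miR-214-5p with miR-3120-3p, miR-423-5p with miR-3184-3p, miR-423-3p with miR-3184-5p, miR-374b-5p with miR-374c-3p, miR-548ah-3p with miR-548p, miR-3158-3p with miR-3158-5p, and miR-486-3p with miR-486-5p. Each pair shares at least 18 bases between hairpins on opposite strands, so reads of 1 member cannot be told from reads of the other if strand was not used in counting, and 6 of the 56 calls belong to such pairs. miR-199b-3p stood at 0.493 to 0.506 of miR-199a-3p in every library, and these 2 names share a mature sequence.

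**Figure D4:**
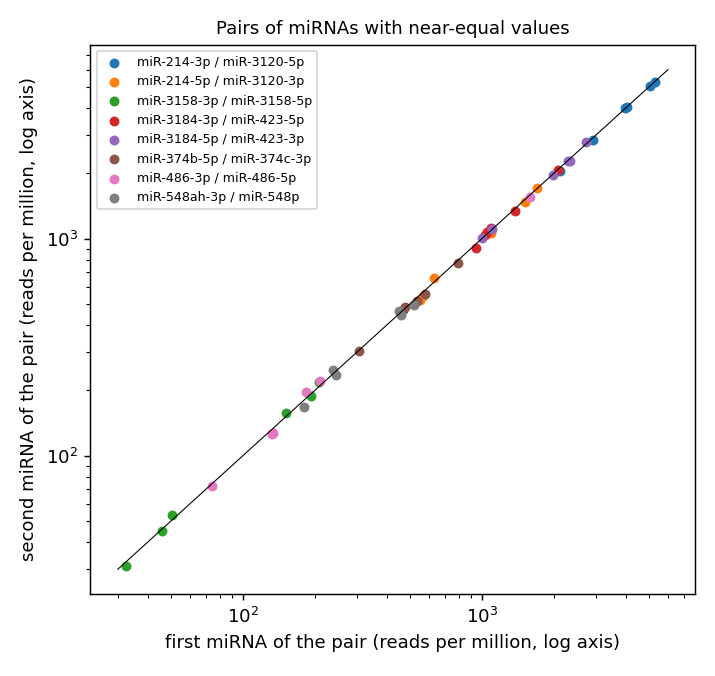
RPM of the second against the first member of 8 pairs of miRNAs (both axes log), with 6 points per pair, 1 for each library, and a line of equal values. All points lie within 10% of the line, from miR-3158 near the lower end to miR-214-3p with miR-3120-5p at the upper end.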

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

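Of the tests in this part, those of the per-million total, of A2780 RNA and of blood RNA in A2780-DDP replicate 2 were chosen only after the result was seen, as were the fits with a GC correction, with near-equal pairs counted once and with median-of-ratios factors without that library. Outside the main measurement, 138 predicted miRNAs below the filter of 10 RPM, which entered no test with that filter, summed to 139 RPM on average over the 6 libraries. The sums were 90.3, 134.6 and 193 RPM in A2780 and 147.7, 117 and 151.6 RPM in A2780-DDP. The limit of 0.763 to 2.26 RPM for a count of 0 applies to a single miRNA. Set against a sum over 138 miRNAs, it cannot show whether they were detected above the floor.

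Decreases outnumbered increases by 42 to 14 in A2780-DDP. With median-of-ratios factors the ratio of lower to higher calls was 1.41, but those factors centre the fold changes, so this does not decide whether abundant miRNAs took more of the per-million total. After rescaling without the 5 most abundant miRNAs the ratio was 2.07 (29 lower, 14 higher), from 1 to 2.46 on leaving out each library, with a median log2 fold change of -0.29, so whether these 5 were the whole cause stays open as well. The miRNAs named as largest decreases kept their direction with those factors, and miR-148a-3p, with a log2 fold change of -2.95, miR-132-5p, with -2.88, and miR-204-5p, with -3.58, stayed past the threshold. A lower level of miRNAs as a group in the resistant line was not tested, since no measure of total RNA was analysed here.

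In A2780-DDP replicate 2, which lay apart from replicates 1 and 3, 63.6% of 187 miRNAs with a mean of at least 100 RPM lay outside the range of the other 5 libraries, against at most 33.2% for any other library, which argues against A2780 RNA mixed into it as the whole cause, since mixed values would lie between both lines. Its deviation correlated weakly with hairpin GC content across miRNAs (Spearman rho 0.20, permutation p = 2e-04), with rho of -0.12 and -0.23 in replicates 1 and 3, whose deviations are tied to it since the 3 sum to 0, and as miRNAs are not independent replicates and 0.20 lay between the limits of 0.1 and 0.3 fixed for the test, a contribution of GC cannot be told apart from other differences. As the whole cause, a linear effect of hairpin GC is argued against by the 61.8% still outside after correction, with at most 33.9% for the others. The GC content of the mature reads was not available, and both arms of a hairpin were given the same value. The correction therefore cannot decide on recovery that depends on the GC content of the reads themselves. Blood RNA is argued against as the source of its high miR-486, since the other blood miRNAs summed to 2.73 RPM there, below the 7.53 RPM of A2780-DDP replicate 1. A difference in culture or an unrecorded batch stays open, and no biological explanation was tested.

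The 8 pairs with near-equal values all shared at least 18 bases on opposite strands (100%, against 0.25% of 2000 random pairs), as counting regardless of strand would give. The largest difference within a pair ranged from 2.25% to 8.15%, so the rows were not identical. Whether a read was counted under both hairpins or assigned to 1 of them was not tested. Counting each pair once left 52 calls, 14 higher and 38 lower, all among the 56.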

How the results depend on the processing

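Chosen only after the data were seen were the counts with near-equal pairs once, with a GC correction, with median-of-ratios factors without A2780-DDP replicate 2, the lists with an estimated correlation without that library or with no filter, and the tests over splits of the libraries. No pairing of libraries by replicate number was seen (correlations of same-numbered deviations 0.19, -0.19 and -0.21, and no library correlated best with its own number). With 3 libraries of each line this cannot exclude a shared culture or batch. With the replicate block 54 miRNAs passed (17 higher, 37 lower), 49 of them shared, 0 lists passed, and miR-219a-5p had an exact p of 0.25. Against 56 calls (14 higher, 42 lower), a filter of 1 RPM gave 74 (27 higher, 47 lower), a filter of 100 RPM 36 (6 higher, 30 lower), and no filter 61 (24 higher, 37 lower). Median-of-ratios factors gave 41 (17 higher, 24 lower), rescaling without the 5 most abundant 43 (14 higher, 29 lower), quantile normalization 40 (19 higher, 21 lower), edgeR 43 (23 higher, 20 lower) and DESeq2 62 (34 higher, 28 lower). A threshold of 0.01 gave 24 (6 higher, 18 lower) and 0.1 gave 93 (19 higher, 74 lower). Leaving out each library gave 17 to 131 calls, with 5 to 29 higher and 12 to 102 lower, the lowest without A2780 replicate 2 and the highest without A2780-DDP replicate 2; losses may reflect the smaller number of libraries. Median-of-ratios factors without A2780-DDP replicate 2 gave 118 (56 higher, 62 lower), 50 of them shared, and reversed miR-542-3p to 0.78 from -0.13, which had not passed; the cause was not tested. The remaining alternatives gave 52 to 64 calls. Against 2 lists past camera, 0 passed with a filter of 1 or 100 RPM, quantile normalization, an estimated correlation (also without A2780-DDP replicate 2 or with no filter), only the more abundant arm, or the GC correction, 1 with median-of-ratios factors, with or without A2780-DDP replicate 2, or rescaling without the 5 most abundant, 3 with pseudocount 0.1 (miR-30 added), 2 with pseudocount 10, 4 with no filter, and 0 to 3 when leaving out a library. The 4 with no filter were the miR-200 and miR-17-92 lists, lower, and the miR-30 and 14q32 lists, higher, none of them among the 2. Leaving out A2780 replicate 2 or 3 gave 0, A2780-DDP replicate 1 only let-7, A2780-DDP replicate 2 only miR-30, A2780-DDP replicate 3 both lists, and A2780 replicate 1 miR-23, miR-30 and miR-181. Median-of-ratios factors kept let-7, but without A2780-DDP replicate 2 only miR-30 passed; rescaling kept let-7. Against 0 arm ratios, a filter of 100 RPM gave 5, no filter 1, and leaving out a library 0 to 18; the GC correction was not run on them, since both arms share a hairpin. The difference in detected miRNAs turned from 45.3 to -10.3 at 10 RPM and -44.7 with any read, with a range of -12.5 to 90.3 on leaving out a library. The top-10 share difference of 5.68 points stayed between 4.09 and 7.10 on leaving out a library; other cutoffs were 13.2 points for the most abundant miRNA and 2 for the top 50. miR-219a-5p was lower in A2780-DDP in every alternative, from -2.12 with pseudocount 0.1 to -0.18 with pseudocount 10, and -0.62 to -1.17 on leaving out a library. It passed in none, but most of these alternatives were exact permutation tests, which cannot give a p below 0.1 and so could not pass. With a filter of 100 RPM it has no value. For single named miRNAs 2504 results kept their direction and side of the threshold, 63 newly passed, 99 no longer passed and 1 reversed; for lists the counts were 372, 8, 32 and 0. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05: the real split gave 56 miRNAs (highest other 0), 2 lists (highest other 5) and 0 arm ratios (highest other 0), with results as large in 1, 7 and 10 splits. Depth limits miRNAs below about 2.26 RPM, the worth of 3 reads in the shallowest library, A2780-DDP replicate 1.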

Other observations

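The neighbour test in this part was fixed before its result was seen, whereas the miRNAs singled out here and the scan over replicate numbers were chosen after their values were seen. Further decreases in A2780-DDP included miR-425-5p, from 7744 ± 312 to 2216 ± 130 RPM (SD, n = 3 each), a 3.50-fold change (limma Benjamini-Hochberg adjusted p = 0.00122). Its hairpin lies in an intron of DALRD3 on chromosome 3 (49020148 to 49020234, minus strand), where miR-191-5p, from the same host, did not pass at 6747 ± 1594 and 5500 ± 2450 RPM. miR-7706 fell from 227 ± 35.7 to 53.8 ± 12.2 RPM, miR-330-5p from 521 ± 121 to 150 ± 15.0 RPM, miR-345-5p from 192 ± 18.9 to 60.1 ± 7.70 RPM and miR-339-3p from 171 ± 27.6 to 48.8 ± 11.9 RPM, with adjusted p-values of 0.00313 for miR-7706 and 0.00564 for the other 3 in limma with Benjamini-Hochberg adjustment. miR-3923, whose mean was below 10 RPM, fell from 16.3 ± 2.54 to 0.671 ± 1.16 RPM (adjusted p = 0.00769, limma with Benjamini-Hochberg adjustment), with all of its A2780-DDP reads in replicate 3. miR-378a-3p, at 25330 ± 2457 and 14050 ± 2078 RPM, passed in deposited RPM (adjusted p = 0.0277, limma, Benjamini-Hochberg) but not with median-of-ratios factors (adjusted p = 0.244).

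The large increases miR-3118 and miR-5701 share a neighbourhood. All 3 hairpin genes of miR-5701 lie on chromosome 15, starting at 20940252, 21513959 and 21951242, and 3 of the 4 of miR-3118 lie near them, starting at 20832795, 21406385 and 21843750 on the same strand. The 4 hairpins of miR-3118 include 1 on chromosome 21. miR-5701 was at 463, 131 and 491 RPM in A2780-DDP replicates 1, 2 and 3, and miR-3118 at 42.2, 68.8 and 38.6 RPM, so the ratio between them differed in replicate 2.

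A hypothesis that hairpins within 10 kb of each other on 1 strand change together was tested over 250 hairpins. The mean absolute difference of log2 fold change was 0.600 over 70 neighbouring pairs and 0.967 after permuting values over hairpins (permutation p = 0.0028). Transcripts shared by neighbours would give such a difference. Values were permuted over all 250 hairpins, so a narrower spread of changes among hairpins with neighbours would lower it too. The test cannot tell these apart. miR-143 with miR-145 and miR-132 with miR-212 were examples of neighbours that both passed, whereas miR-425-5p passed and its neighbour miR-191-5p did not, a difference that was not tested.

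miR-27a-3p was uneven within both lines, at 5208, 1270 and 974 RPM in A2780 replicates 1, 2 and 3 and 6084, 1580 and 1280 RPM in A2780-DDP replicates 1, 2 and 3. It was the only tested miRNA at least 2 times above both other libraries in replicate 1 of both lines, and the same search over the other 8 combinations of replicates found 0 to 2 miRNAs each. Below the filter, the 14q32 imprinted cluster summed to 11.04 ± 6.63 RPM in A2780 and 41.6 ± 33.2 RPM in A2780-DDP (exact permutation p = 0.1, the smallest possible with n = 3), the 19q13 cluster to 22.8 ± 6.35 and 18.2 ± 13.01 RPM (exact permutation p = 0.7), and pluripotency miRNAs to 3.01 ± 3.19 and 14.6 ± 7.78 RPM (exact permutation p = 0.1). The miR-506 clusters summed to 15.3 ± 2.20 and 33.1 ± 24.6 RPM (exact permutation p = 0.2). A2780-DDP replicate 1, the library with the fewest reads, held 79.9 RPM of the 14q32 cluster and 61.0 RPM of the miR-506 clusters, and the A2780-DDP means without it were 22.5 and 19.1 RPM. With no filter the 14q32 list passed higher in camera (adjusted p = 0.0488, Benjamini-Hochberg), but not with an estimated correlation (0.670). It also held the most of the 19q13 cluster and of the pluripotency miRNAs, whose means without it were 10.7 and 10.95 RPM. Striated muscle miRNAs summed to 17.5 ± 1.47 and 15.3 ± 6.69 RPM. The liver miRNA miR-122 summed to 0.174 ± 0.151 and 1.66 ± 1.99 RPM, and to 0.5205 RPM without A2780-DDP replicate 2, which held 3.94 RPM.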
